A study of Bos taurus and Bos indicus with 12 samples.

How the data were processed

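Punch biopsies of whole skin from 12 female cattle were each hybridised to 1 Affymetrix bovine expression array. Of the 6 animals of each breed, 3 had never met ticks and 3 were infested. Naive Holstein-Friesian animals were 12 months old, naive Brahman animals 18 months and all infested animals 6 months. Infestation was therefore confounded with age within each breed, and only the infested groups were of the same age.

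The deposited values are log2 expression values, 1 per probe set and array, made by the authors with RMA (robust multi-array average), per the submitters' processing notes. The RMA software, its version and the chip definition are not given in the sources used here. The log2 scale was read from the values. The array medians lay between 6.576 and 6.729 log2. The deposited table held 24128 probe sets. The 112 control probe sets were left out of the tests, and 24016 were tested with no filter on low signal. Gene names came from the platform annotation: 13292 tested probe sets had 1 gene symbol, 86 had several and 10638 had none. The gene ID of 13263 probe sets was found in the RefSeq gene table, and no symbol needed an update. Probe sets with several symbols were not named. Detection calls were not used here, so signal over background is unknown, and the number of arrays limits the precision.

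All 12 arrays entered 1 linear model of 4 group means in limma 3.58.1 under R 4.3.3, with 8 residual and 3.03 prior degrees of freedom. Moderated statistics came from lmFit and eBayes, and p-values were adjusted by Benjamini-Hochberg within each of 5 comparisons, with a threshold of 0.05. The comparisons were infested against naive animals in each breed, the difference between the breeds in that effect, and Brahman against Holstein-Friesian among naive and among infested animals. All tests were two-sided. Because the model pools the spread, the standard error of a probe set was the same in each comparison of 3 against 3 arrays.

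The 30 gene lists, with 596 measured memberships, were fixed before the data were examined, as were the comparisons, the tests and all other settings except the 3 named last below. Each list was tested with limma's camera at an inter-gene correlation of 0.01, on the probe set with the highest mean for each gene, and adjusted over the 30 lists of a comparison. Camera with an estimated correlation and fry were alternatives. A list median is the median log2 difference over its measured members, and a list level is the mean over members of the array's value minus the mean of the 6 naive arrays. Named genes followed a fixed rule: up to 10 with the largest rise and 10 with the largest fall among probe sets past the threshold whose groups did not overlap, and up to 4 members of each list, those past the threshold first. Where no gene passed in a direction, the 5 with the smallest p were taken and are reported as not passing. C3, ARHGEF37, NDRG1, MPC1 and MARF1 entered in that way. Where probe sets of a named gene passed in opposite directions, this is stated.

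RNA integrity was read from 5 control transcripts with probe sets at both ends, namely GAPDH, EF1A, cyclophilin, EIF4E and GST. The index is the mean of their 5' minus 3' log2 signals, and a lower index means less signal from the 5' end. The labels record no hybridisation date or batch.

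Replicate numbers were shared by the 4 groups. Deviations from the group means correlated by 0.113 to 0.249 between same-numbered arrays of naive and infested Holstein-Friesian animals, and each of these 6 arrays correlated best with its own number. The rule fixed for this check takes such numbers as paired, although the animals differed in age and no label explains it. In none of the other 5 pairs of groups did every same-numbered correlation exceed 0.1. Same-numbered arrays of naive and infested Brahman animals correlated by -0.189 to -0.053, and none correlated best with its own number. Deviations within a group cancel out, so chance alone can match every number in a pair of groups. The check therefore cannot tell a pairing from chance, and the replicate block was kept as an alternative setting. Any 2 arrays shared at most 0.104% of their values, so no array repeated another.

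The alternatives were a low-signal filter at the 40 percent quantile of mean signal, median centring, cyclic loess, a trended and robust prior, only the 6 arrays of a comparison, array weights, a replicate block, leaving out each array, and for lists the mean of all probe sets of a gene. Leaving out the 2 arrays with the lowest index, the index as a covariate, and the replicate block in the 6 Holstein-Friesian arrays alone were added after seeing the data. The procedure was tested on simulated data with the real means and residual spreads of 24016 probe sets and independent errors. It recovered 53.0% of changes of 1 log2 and 90.0% of changes of 2 log2 in the comparison of infested with naive Holstein-Friesian animals, and 49.5% and 88.0% in that of infested with naive Brahman animals. For the difference between breeds it recovered 13.0% and 79.0%. Among naive breeds it recovered 37.0% and 87.9%, and among infested breeds 54.0% and 85.0%. In each comparison 99 or 100 probe sets changed at each size, and 4 to 11 unchanged ones were called. All simulated arrays had the same spread, whereas the weights of the real arrays ran from 0.187 to 3.724. The number of real changes also differed, so these shares may not hold for the real data. Figures were drawn with matplotlib 3.10.9.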

Results

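Gene expression was measured in the skin of 12 cattle of 2 breeds, before exposure to the cattle tick Rhipicephalus microplus or after successive heavy infestations. Holstein-Friesian is a taurine dairy breed, and Brahman is an indicine (zebu) beef breed known for its resistance to this tick. Biopsies of infested animals were taken where larvae were attached. Each of the 4 groups held 3 animals with 1 array each, and values are RMA expression on the log2 scale with n = 3 arrays per group throughout. The 12 animals were separate, so the spread includes differences between animals.

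The arrays differed in RNA integrity. The mean 5' minus 3' index was -1.13 ± 0.29 log2 (SD, n = 3) in naive Holstein-Friesian and -0.94 ± 0.10 in naive Brahman animals. It was -1.57 ± 1.04 in infested Holstein-Friesian and -3.18 ± 1.52 in infested Brahman animals. Among the infested Holstein-Friesian arrays the index was -2.73 in array 1, -0.74 in array 2 and -1.23 in array 3. Infested Brahman arrays 1, 2 and 3 had -4.91, -2.56 and -2.07, all below the lowest naive array at -1.39. The first principal component, with 42.3% of the variance, separated the infested from the naive arrays, and infested Brahman 1 stood apart on the second, with 17.5%.

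**Figure D1:**
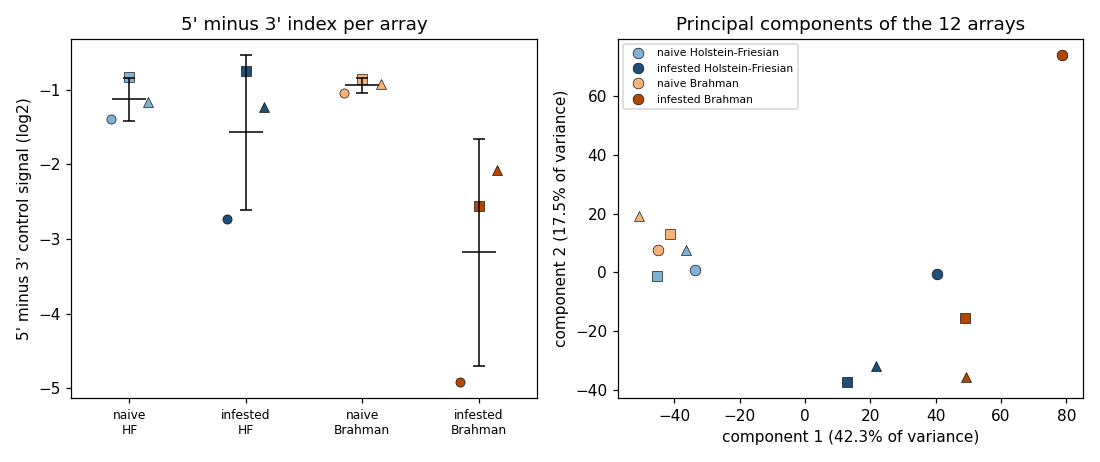
Left, the 5' minus 3' index (log2) of each array by group, with circle, square and triangle for replicates 1, 2 and 3 and bars for the mean ± SD of 3 arrays (HF, Holstein-Friesian); the infested Brahman arrays lie between -4.91 and -2.07. Right, the arrays on principal components 1 and 2, in arbitrary units, with 42.3% and 17.5% of the variance; infested arrays lie to the right, and infested Brahman 1 stands apart at the top.

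The first comparison asks which genes differ in tick-infested Holstein-Friesian skin. The neutrophil-attracting chemokine genes CXCL5, CXCL2 and CXCL8 and the collagenase gene MMP1 were among the genes that rose most in infested animals, and PGLYRP1 and TDO2 were among those that fell most. CXCL5 rose from 5.26 ± 0.30 to 9.76 ± 0.32 (SD), a log2 change of 4.50 ± 0.79 (SE, adjusted p = 0.0149). CXCL2 rose 19.4-fold, or 8.64-fold without infested Holstein-Friesian 2 and 30.0-fold without infested Holstein-Friesian 3. CXCL8, the chemokine also called interleukin 8, rose by 3.55 ± 0.84, by 4.51 without infested Holstein-Friesian 1 and by 2.80 without infested Holstein-Friesian 2, when it did not pass (adjusted p = 0.111). The interstitial collagenase MMP1 rose 17.6-fold and CD5L, a secreted macrophage protein, 11.6-fold (adjusted p = 0.000521). The immunoglobulin gamma constant region gene IGCGAMMA rose by 3.86 ± 0.98, by 4.99 without naive Holstein-Friesian 2, and did not pass without naive Holstein-Friesian 1 (3.17) or infested Holstein-Friesian 2 (3.27). The eosinophil chemokine CCL26 rose by 3.00 ± 0.59.

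PGLYRP1, which encodes a peptidoglycan recognition protein, fell 54.5-fold from 13.65 ± 0.23 to 7.88 ± 0.49 (adjusted p = 0.000521). TDO2, the tryptophan dioxygenase, fell 26.9-fold, with a log2 change of -4.75 ± 1.11. HSD17B2, an enzyme of sex steroid inactivation, fell 7.77-fold, the lipogenic regulator THRSP 5.21-fold and the quinone reductase NQO1 5.08-fold. HOXA9 fell by 4.23 ± 0.92 and HMGA1 by 2.70. One of 2 RAC3 probe sets fell by 2.32, and the other stood at 0.04. One of 5 GSTA2 probe sets fell by 2.92, and the highest of the others, which did not pass, stood at 1.79. One probe set of the matrix glycoprotein gene THBS1 fell by 3.09 while another of its 6 rose by 1.56, so its direction is open. LYVE1 of lymphatic endothelium rose 8.53-fold, and SAMSN1 and APOD rose 7.05-fold and 6.64-fold. The other of 2 SAMSN1 probe sets did not pass, at 1.13 log2.

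Of 24016 probe sets, 1206 changed in Holstein-Friesian animals by limma, 644 higher and 562 lower, and 391 and 237 of these changed at least 2-fold. With each array centred on its median, 679 were higher and 392 lower. The arrays of the 2 groups did not overlap for 30.3% of probe sets, where chance gives 10%. The count was 4076 without the 2 arrays of lowest index and 2022 with the index as a covariate. Leaving out 1 array at a time gave 157 without naive Holstein-Friesian 1 to 2563 without infested Brahman 1. Of 74 named genes past the threshold, 15 passed whichever array was left out, and 59 did not pass without at least 1 of them. With the replicate block, which takes up what same-numbered arrays share, 61 of the 74 kept their call and 13 lost it. IGCGAMMA was among those that lost it (adjusted p = 0.0541). With the block in the 6 arrays alone 68 genes kept their call and 6 lost it, among them PLAT and UQCRB. Infested animals were 6 months younger than naive ones, so age is not separated from infestation here.

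Camera called 16 of the 30 gene lists in Holstein-Friesian animals, 11 higher and 5 lower, and none with an estimated correlation. With the replicate block 15 of the 16 kept their call and 1 lost it. The macrophage and dendritic cell list had a median of 1.37 log2, with 7 of 19 members higher and 1 lower (adjusted p = 4.7e-08; adjusted p = 0.269 with an estimated correlation). Adjusted over the list alone, 14 were higher and 1 lower. CD209, a lectin of dendritic cells and macrophages, rose 6.24-fold and the scavenger receptor MSR1 3.55-fold, and the inhibitory Fc receptor gene FCGR2B fell 3.98-fold. For MSR1 1 of 3 probe sets passed, and the lowest stood at 0.24 log2. In the list of collagens and matrix, 8 of 33 members rose and none fell, with a median of 0.49 (adjusted p = 8.29e-08; adjusted p = 0.0538 with an estimated correlation). THBS2 rose 3.48-fold, the small proteoglycan OGN 3.42-fold and the elastic fibre gene FBLN5 3.03-fold. Matrix proteases and inhibitors had 5 of 22 members higher, among them the cysteine protease CTSK at 4.17-fold (adjusted p = 6.27e-06; adjusted p = 0.0538 with an estimated correlation).

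Complement genes had 5 of 23 members higher and none lower, with a median of 0.69 (adjusted p = 1.83e-05; adjusted p = 0.269 with an estimated correlation). C1QA rose 5.41-fold, or 8.13-fold without naive Holstein-Friesian 2, C1QB 3.68-fold and C3 2.90-fold. Of 13 genes for MHC class II antigen presentation, 4 rose, including CTSS at 3.53-fold and BOLA-DRB3 at 2.71-fold (adjusted p = 0.00118; adjusted p = 0.269 with an estimated correlation). Coagulation and fibrinolysis had 6 of 24 members higher, led by F13A1 at 5.44-fold and the plasminogen activator PLAT at 3.76-fold (adjusted p = 0.00123; adjusted p = 0.351 with an estimated correlation). The list of type 2 immunity had 2 of 20 members higher, CCL26 and the stem cell factor receptor KIT at 3.41-fold (adjusted p = 0.00139; adjusted p = 0.27 with an estimated correlation). For KIT 1 of 4 probe sets passed, and the lowest stood at 0.03 log2. Inflammatory cytokines and chemokines had 4 of 27 members higher and a median of 1.05 (adjusted p = 8.1e-06; adjusted p = 0.351 with an estimated correlation). The list level was 2.60 in infested Holstein-Friesian 2, against 0.66 and 0.75 in arrays 1 and 3. The list median was 0.22 without that array and 1.59 without infested Holstein-Friesian 1, and without the 2 arrays of lowest index 11 members were higher. The genes CXCL5, CXCL2, CXCL8 and the interleukin 1 antagonist IL1RN were the members that passed with all arrays.

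Fatty acid synthesis and sebaceous gland genes had 5 of 24 members lower and none higher, with a median of -0.54 (adjusted p = 0.00139; adjusted p = 0.141 with an estimated correlation). The elongase ELOVL6 fell 3.95-fold and the desaturase SCD 3.75-fold. The list level lay between -0.61 and -0.59 in the 3 infested arrays. Oxidative phosphorylation genes had 2 of 39 members lower, SDHA and UQCRB, with a median of -0.26 (adjusted p = 0.000335; adjusted p = 0.351 with an estimated correlation). Without the 2 arrays of lowest index the median was -0.17, through infested Holstein-Friesian 1, and 8 members were lower. The other lists past the threshold held at most 2 called members each, and the T cell, cell cycle and smooth muscle lists held none. As lists, neutrophil, B cell and plasma cell, and T cell genes were higher, and cell cycle, smooth muscle and cholesterol synthesis genes were lower. Their adjusted p with an estimated correlation lay between 0.351 and 0.537. Without naive Holstein-Friesian 3 none of these 6 lists passed but the cell cycle, which did not pass without naive Holstein-Friesian 2. In B cell genes the plasma cell gene MZB1 rose 4.96-fold. Glandular epithelium did not pass as a list (adjusted p = 0.0706), but did without naive Holstein-Friesian 2 or naive Brahman 2, and KRT19, AZGP1 and KRT7 fell 4.56-fold, 3.83-fold and 3.55-fold.

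**Figure D2:**
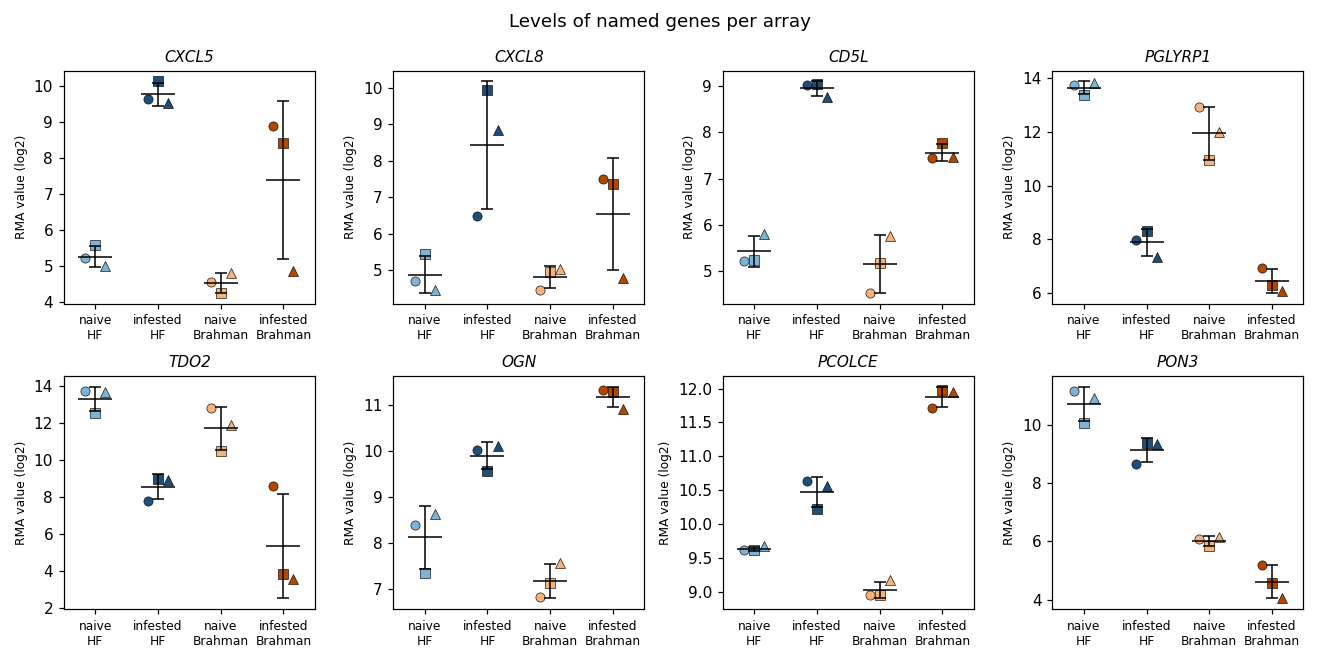
RMA values (log2) of 8 named genes in each array, by group (HF, Holstein-Friesian), with circle, square and triangle for replicates 1, 2 and 3 and bars for the mean ± SD of 3 arrays. CXCL5 stood at 9.76 ± 0.32 in infested Holstein-Friesian animals and spread from 4.87 to 8.88 in infested Brahman animals, while PGLYRP1 fell in both breeds.

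The second comparison asks the same of Brahman skin. The matrix genes KERA and OGN were among the genes that rose most in infested Brahman animals, and TDO2 and PGLYRP1 were among those that fell most. The corneal and dermal proteoglycan gene KERA rose 17.5-fold from 7.99 ± 0.54 to 12.12 ± 0.65 (SD, adjusted p = 0.000713). OGN rose 16.0-fold and PCOLCE, which enhances procollagen processing, 7.21-fold, from 9.03 ± 0.12 to 11.88 ± 0.15 (adjusted p = 1.32e-05). The other of its 2 probe sets rose by 1.42 log2. One of 2 probe sets of CCDC80, a matrix protein gene, rose 8.49-fold, and the other did not pass at 0.45 log2. GNB4 rose 11.6-fold and IGSF10 10.5-fold. The keratin gene KRT6B rose by 3.10 ± 0.95, to 10.69, 10.05 and 11.22 in the infested Brahman arrays. It already stood at 11.45, 13.08 and 8.03 in the naive Holstein-Friesian arrays, so a high level did not require infestation. The water channel AQP5 rose by 2.79 ± 0.61, or by 3.66 without infested Brahman 1. CXCL5 rose by 2.85 ± 0.79, with values of 8.88, 8.40 and 4.87 in the 3 infested arrays. Its change was 4.10 without infested Brahman 3 and 2.10 without infested Brahman 1, when it did not pass (adjusted p = 0.0723). One probe set of BOLA-DQB1, an MHC class II gene that is highly polymorphic, rose by 3.94 ± 1.24, or by 5.11 without naive Brahman 2, and its 5 probe sets ranged from -1.35 to 4.26.

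PGLYRP1 fell 45.2-fold in Brahman animals and TDO2 82.6-fold, with TDO2 at 8.58, 3.86 and 3.59 in the infested arrays. The TDO2 fall was 254-fold, 49.4-fold and 45.0-fold without infested Brahman 1, 2 and 3, and 127-fold without naive Brahman 2. HPD, an enzyme of tyrosine breakdown, fell 29.4-fold, with 4.66, 6.32 and 7.60 in the infested arrays. Its fall was 17.3-fold without infested Brahman 1, 47.9-fold without infested Brahman 3 and 44.4-fold without naive Brahman 2. FMO5, LY75 and CYBRD1 fell by 4.17, 3.87 and 3.81 on the log2 scale. For FMO5 3 of 5 probe sets passed, and the highest of the 5 stood at -0.22. For CYBRD1 1 of 2 passed, and the other stood at -0.28. MIF fell 13.8-fold, or 7.76-fold without infested Brahman 1 and 34.8-fold without infested Brahman 2. The phosphatase gene PPP1CB fell by 4.39 ± 0.84, the splicing factor gene SRSF1 by 3.92 ± 0.74 and the fumarase gene FH by 3.79 ± 0.64. For SRSF1 2 of 3 probe sets passed, and the highest of the 3 stood at -0.17. For FH 2 of 2 passed, the other at -0.73. PPP1CB was at 5.72, 5.40 and 5.57 in the infested Brahman arrays and at 5.0 in infested Holstein-Friesian 1, but at 9.36 and 8.11 in infested Holstein-Friesian 2 and 3. Its other 2 probe sets did not pass, and the highest of the 3 stood at 0.16.

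In Brahman animals 4753 of 24016 probe sets changed by limma, 2292 higher and 2461 lower, and 1014 and 1344 of these changed at least 2-fold. With each array centred on its median, which moved the median of all probe sets by 0.14 log2, 3002 were higher and 1983 lower. The arrays of the 2 groups did not overlap for 38.5% of probe sets, where chance gives 10%. The count was 6255 without the 2 arrays of lowest index and 1808 with the index as a covariate, of which 1091 were among the 4753. Leaving out 1 array at a time gave 2216 without naive Brahman 3 to 5567 without infested Holstein-Friesian 1. Of 92 named genes past the threshold, 48 passed whichever array was left out, and 44 did not pass without at least 1 of them. With the index as a covariate 34 of the 92 kept their call, among them KERA, OGN, PCOLCE, TDO2 and PGLYRP1, and 58 lost it, among them CXCL5, KRT6B, PPP1CB, SRSF1, FH, MIF, CIDEA, ELOVL1, CYC1 and C3. In addition, 31 of the 112 control probe sets passed in Brahman and 0 in Holstein-Friesian animals. Of 266 genes with at least 2 called probe sets, 85 (32.0%) had calls in both directions, against 4 of 42 (9.52%) in Holstein-Friesian animals. Infested Brahman animals were 6 and naive ones 18 months old.

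Camera called 8 lists in Brahman animals, 5 higher and 3 lower. Collagens and matrix had 19 of 33 members higher and none lower, with a median of 0.80 (adjusted p = 1.11e-10; adjusted p = 0.0286 with an estimated correlation). Besides OGN and PCOLCE, the fibril collagen gene COL5A2 rose 5.95-fold and the proteoglycan LUM 5.37-fold. The list level was 0.59, 0.95 and 1.07 in the infested arrays, against -0.22, -0.07 and -0.10 in the naive ones. Imprinted and growth genes whose expression declines after birth had 6 of 16 members higher, among them 1 of 2 SGCE probe sets at 3.09-fold (the other at -0.39 log2) and PLAGL1 at 2.21-fold (adjusted p = 0.00205; adjusted p = 0.0741 with an estimated correlation). Coagulation genes had 6 of 24 members higher, with F13A1 at 4.96-fold, 1 of 2 PROS1 probe sets at 3.95-fold (the other at -0.23 log2) and the protein C receptor PROCR at 3.18-fold (adjusted p = 0.00382; adjusted p = 0.593 with an estimated correlation). Macrophage genes had 3 of 19 members higher and 1 lower, with 1 of 3 MSR1 probe sets at 4.39-fold (adjusted p = 0.0081; adjusted p = 0.677 with an estimated correlation). Complement had 2 of 23 higher, C1QB and C3 (adjusted p = 0.0242; adjusted p = 0.677 with an estimated correlation). The macrophage and complement medians of 0.56 and 0.39 were 0.24 and 0.17 without infested Brahman 1, and neither list then passed. Complement also did not pass without infested Brahman 3, at 0.37.

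Oxidative phosphorylation genes had 17 of 39 members lower and none higher in Brahman animals, with a median of -0.51 (adjusted p = 4.34e-07; adjusted p = 0.439 with an estimated correlation). SDHA fell 1.96-fold. CYC1 fell 3.22-fold, or 1.97-fold without infested Brahman 1, and 1 of 3 NDUFS1 probe sets fell while another rose. Fatty acid synthesis and sebaceous gland genes had 11 of 24 lower and 2 higher, with a median of -0.78 (adjusted p = 0.00134; adjusted p = 0.105 with an estimated correlation). Malic enzyme ME1 fell 4.57-fold. CIDEA fell 6.76-fold and ELOVL1 5.44-fold, and these falls were 3.08-fold and 2.95-fold without infested Brahman 1, the array of lowest index. The CIDEA fall was 10.2-fold without infested Brahman 3. Skeletal muscle genes had 7 of 30 lower and 1 higher (adjusted p = 0.00128; adjusted p = 0.677 with an estimated correlation). One of 3 MYBPC1 probe sets fell 5.89-fold, or 8.89-fold without naive Brahman 1. The muscle list level was 0.79 and 1.29 in naive Brahman 2 and 3, against -0.74 in naive Brahman 1, and -0.62, -0.60 and -0.76 in the infested arrays. Inflammatory cytokines did not pass as a list in Brahman animals, with a median of 0.35 and 2 of 27 members higher (adjusted p = 0.101). They passed without infested Brahman 3 (0.44) and, as a separate setting, without infested Holstein-Friesian 2. They also passed with the index as a covariate (0.58) and with the mean of all probe sets of a gene. The median was 0.14 without infested Brahman 1 and 0.21 without naive Brahman 2.

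**Figure D3:**
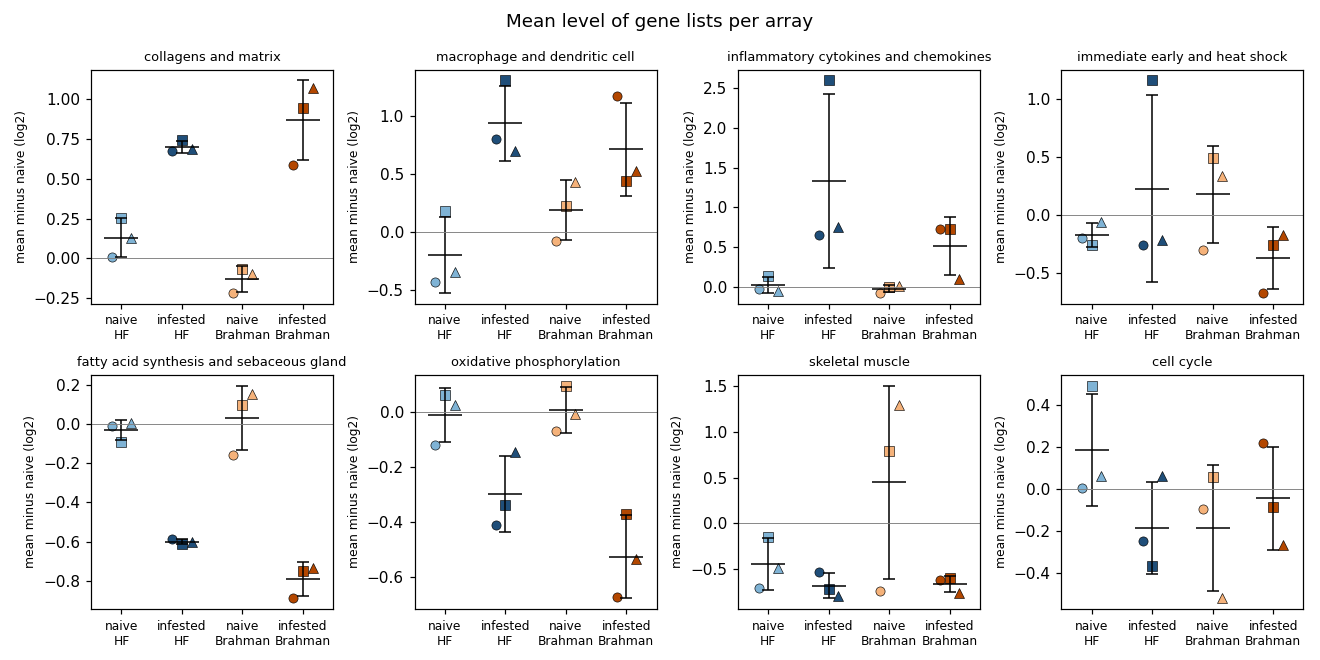
Mean level of 8 gene lists in each array (log2, relative to the mean of the 6 naive arrays), by group (HF, Holstein-Friesian), with circle, square and triangle for replicates 1, 2 and 3 and bars for the mean ± SD of 3 arrays. The inflammatory list reached 2.60 in infested Holstein-Friesian 2 alone, and the muscle list 0.79 and 1.29 in naive Brahman 2 and 3.

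The third comparison asks whether the breeds differ in the infestation effect. Naive and infested ages lay further apart in Brahman (18 and 6 months) than in Holstein-Friesian (12 and 6), so age could enter this difference. PCOLCE was the gene that passed: it rose by 2.85 ± 0.14 in Brahman animals and from 9.63 ± 0.03 to 10.47 ± 0.23 in Holstein-Friesian animals. The difference of 2.01 ± 0.20 log2 (SE, adjusted p = 0.019; 0.1 with the replicate block, range over settings 0.00113 to 0.119) was 1 call among 24016 probe sets by limma, while 1792 had an unadjusted p under 0.05. The other PCOLCE probe set differed by 1.19 and did not pass, and it rose by 1.42 in Brahman animals. No other gene passed. The 5 genes with the smallest p among those with a lower Brahman effect are given here as not passing. One of 3 probe sets of complement C3 differed by -1.76 ± 0.26 (adjusted p = 0.13), ARHGEF37 by -1.55 ± 0.23 (adjusted p = 0.13), NDRG1 by -1.38 ± 0.23 and MPC1, a mitochondrial pyruvate carrier gene, by -1.43 ± 0.27 (both adjusted p = 0.227). MARF1 differed by -2.28 ± 0.47 (adjusted p = 0.315). On the side of a higher Brahman effect, DSC2, a desmosomal cadherin gene, differed by 1.58 ± 0.29 (adjusted p = 0.227) and OGN by 2.22 ± 0.45 (adjusted p = 0.293).

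The number of calls for the difference between breeds varied with the arrays used. It was 1131 without the 2 arrays of lowest index and 390 without infested Holstein-Friesian 1 alone, and it was 0 with the replicate block or without any single naive Holstein-Friesian array. The infestation changes of the breeds, which share no arrays, correlated across probe sets, which are not independent, with r = 0.705. Of the probe sets that changed in Holstein-Friesian animals, 97.8% had the same sign in Brahman animals. Both breeds shared 474 rises and 421 falls, where independent lists of these sizes would share 61.5 and 57.6, and 3 probe sets changed in opposite directions. Both lists rest on the same estimate of the spread of each probe set, so independent lists are not a strict baseline. In both breeds infested animals were also younger and had a lower mean index, so the shared changes cannot be assigned to ticks alone.

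Camera called 11 lists for the difference between breeds, 3 higher and 8 lower in the Brahman effect, and none with an estimated correlation. With the index as a covariate 5 of the 11 kept their call and 6 lost it. Collagens and matrix were higher by a median of 0.52 (adjusted p = 2.3e-05; adjusted p = 0.13 with an estimated correlation), with PCOLCE as the 1 member called over all probe sets. The median was 0.19 without infested Brahman 3 and 0.33 without naive Holstein-Friesian 2. Adjusted over the list alone, 10 of 33 were higher and 1 lower. Growth genes that decline after birth were higher by 0.36 (adjusted p = 0.00472; adjusted p = 0.13 with an estimated correlation). The cell cycle list was higher by 0.57 with no member called (adjusted p = 1.17e-05; adjusted p = 0.544 with an estimated correlation), or by 0.36 without naive Brahman 3. With all arrays the cell cycle and macrophage differences lay more in the naive than in the infested animals, and neither list passed between the infested breeds. Without the 2 arrays of lowest index, macrophage genes were lower in infested Brahman by -0.515 and passed (adjusted p = 0.0163 by camera). That setting dropped infested Brahman 1, whose macrophage level of 1.173 exceeded the 0.445 and 0.527 of infested Brahman 2 and 3. Inflammatory cytokines were lower by -0.67 (adjusted p = 0.00657; adjusted p = 0.605 with an estimated correlation), but the median was 0.06 without infested Holstein-Friesian 2, -0.45 and not passing without infested Brahman 3, and -1.03 without infested Holstein-Friesian 1. MHC class II and macrophage genes, at -0.62 and -0.70, did not pass without infested Holstein-Friesian 2 either, with medians of -0.38 and -0.46. Macrophage genes also did not pass without infested Brahman 2 (-0.52). The adjusted p of MHC class II and macrophage genes with an estimated correlation were 0.455 and 0.572. No member of these lists was called for the difference.

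**Figure D4:**
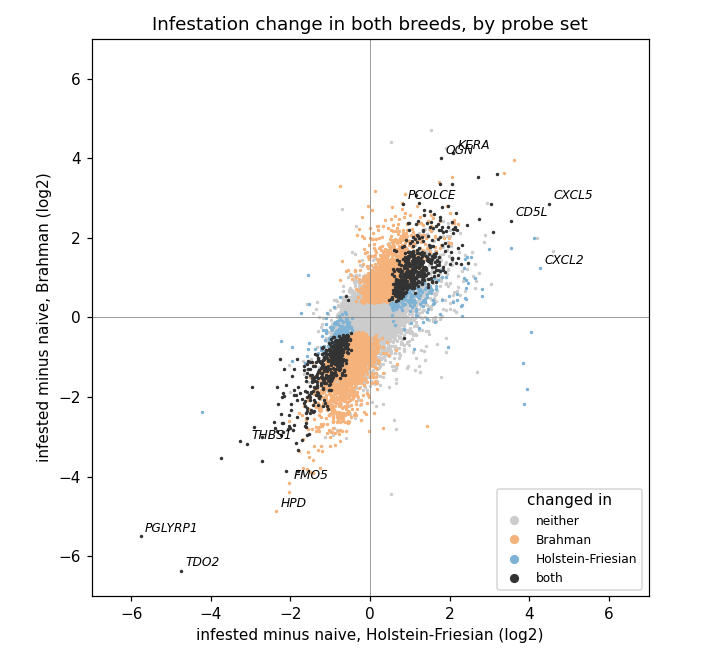
Each point is 1 of 24016 probe sets, with the infested minus naive change in Holstein-Friesian (horizontal) and Brahman animals (vertical) in log2, coloured by the comparison in which it passed limma's adjusted p threshold of 0.05. Most points lie along a rising band (r = 0.705 across probe sets), with PGLYRP1 and TDO2 at its lower end.

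The fourth comparison sets naive Brahman against naive Holstein-Friesian skin. ALOX12E, a lipoxygenase gene, was 17.6-fold higher in naive Brahman animals, at 10.96 ± 0.24 against 6.82 ± 0.32 (SD, adjusted p = 0.00016). CYP4A11, a fatty acid hydroxylase gene, was 6.38-fold higher, and PON3, a lactonase gene, was 25.8-fold lower (adjusted p = 0.000215). One probe set of the transcription factor gene FOXP1 was lower by -2.12 ± 0.20, while the other stood at 1.57 without passing. In all, 6 probe sets passed by limma, 3 higher and 3 lower, with 1149 at an unadjusted p under 0.05 and 66 passing without the 2 infested arrays of lowest index. Leaving out naive Brahman 1 raised the count to 37. The naive groups differed in age, 18 against 12 months.

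Camera called 6 lists between the naive breeds, in which no member passed on its own and none held with an estimated correlation. Skeletal muscle genes were higher in Brahman by a median of 0.67 (adjusted p = 6.39e-12; adjusted p = 0.637 with an estimated correlation), through naive Brahman 2 and 3, or by 0.37 without naive Brahman 3. Macrophage genes were higher by 0.41 and immediate early and heat shock genes by 0.29 (adjusted p = 0.779 and adjusted p = 0.79 with an estimated correlation). Cell cycle, collagen and growth genes were lower by -0.38, -0.23 and -0.20 (adjusted p = 0.637, adjusted p = 0.236 and adjusted p = 0.216 with an estimated correlation). The macrophage list did not pass without naive Holstein-Friesian 1 or 3, and its median was 0.65 without naive Brahman 1 and 0.63 without naive Holstein-Friesian 2. The immediate early list did not pass without naive Holstein-Friesian 1 or 2 or naive Brahman 2 (0.13) or 3. The cell cycle median was -0.22 without naive Brahman 3 and -0.215 without naive Holstein-Friesian 2.

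The fifth comparison sets infested Brahman against infested Holstein-Friesian skin, both at 6 months. The breed genes of the naive animals recurred: ALOX12E was 5.48-fold and CYP4A11 3.06-fold higher in Brahman, and PON3 was 22.9-fold lower (adjusted p = 0.000778). PCOLCE was 2.66-fold higher (adjusted p = 0.00411), CCDC80 3.14-fold and OLFML3, another secreted matrix protein gene, 2.75-fold. The other probe sets of PCOLCE and CCDC80 did not pass, at 0.79 and -0.15 log2. PARM1, CYP39A1, DSC2 and PRPF39 were higher by 2.83-fold, 2.88-fold, 2.66-fold and 2.64-fold, the last by 1 of 2 probe sets. One of 2 probe sets of SYT4, a synaptotagmin gene, was 54.0-fold lower in Brahman, at 4.21 ± 0.35 against 9.97 ± 1.28, and stood at 7.86, 4.43 and 4.46 in the 3 naive Brahman arrays. Without infested Holstein-Friesian 2 it was 33.1-fold lower and did not pass (adjusted p = 0.133). One C3 probe set was 3.59-fold lower, and its other 2 did not pass. BOLA-DYB was 4.71-fold lower, MPC1 2.42-fold and ARHGEF37 2.10-fold. The FOXP1 probe sets went apart, by 2.36 ± 0.29 and -2.59 ± 0.20. Whether breed variants lie under these probe sets, or under those that differed between the naive breeds, was not checked. Breed differences of single probe sets may therefore lie in hybridisation instead of expression.

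Between the infested breeds 40 probe sets passed by limma, 30 higher and 10 lower in Brahman, and 5 of these had passed in the naive breeds. The arrays did not overlap for 13.4% of probe sets, where chance gives 10%. The count was 2200 without the 2 arrays of lowest index, 1235 without infested Holstein-Friesian 1, 156 without infested Brahman 1 and 11 without infested Holstein-Friesian 2. In a fit of only these 6 arrays 1 probe set passed. Of 17 named genes past the threshold, 7 passed whichever array was left out, and 10 did not pass without at least 1 of them. With the index as a covariate 9 of the 17 kept their call and 8 lost it. In the fit of only these 6 arrays none of the 17 kept it.

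Camera called 10 lists between the infested breeds, 2 higher and 8 lower in Brahman, and none with an estimated correlation. With the index as a covariate 1 of the 10 still passed, 8 did not pass and 1 changed sign without passing. Inflammatory cytokines were lower by a median of -0.91 with no member called (adjusted p = 0.000618; adjusted p = 0.456 with an estimated correlation). That median was 0.01 without infested Holstein-Friesian 2, and -0.28 with the index as a covariate, when the list did not pass. Immediate early and heat shock genes were lower by -0.56 with no member called (adjusted p = 0.000618; adjusted p = 0.456 with an estimated correlation), and their level was 1.16 in infested Holstein-Friesian 2 against -0.27 and -0.22 in arrays 1 and 3. The median was -0.10 without that array, and the list did not pass. Melanocyte genes were lower by -0.33, 3 of 13 when adjusted over the list alone and none over all probe sets (adjusted p = 0.000618; adjusted p = 0.173 with an estimated correlation). Collagens and matrix were higher by 0.24, with PCOLCE called (adjusted p = 0.0168; adjusted p = 0.456 with an estimated correlation), and the list did not pass without infested Holstein-Friesian 1, infested Brahman 2 or infested Brahman 3, with medians of 0.155, 0.128 and 0.16. Adipocyte genes were higher by 0.26 (adjusted p = 0.0045; adjusted p = 0.173 with an estimated correlation), or by 0.51 without infested Holstein-Friesian 1 and 0.49 without infested Brahman 3.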

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

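The tests on the inflammatory list, on the collagen list in Holstein-Friesian animals and on age, and both added alternatives that concern the 5' signal, were chosen after the result was seen. The other tests were written down first.

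The infestation effect differed between the breeds by the interaction test for PCOLCE, by 2.01 log2. Naive and infested ages lay further apart in Brahman (18 and 6 months) than in Holstein-Friesian (12 and 6), so age could enter this difference. Between the infested breeds, of the same age, 1 PCOLCE probe set was higher in Brahman by 1.41 log2. With the index as a covariate PCOLCE did not pass for the difference. The permuted residuals of a model without a breed difference in the effect gave as many calls in 3 of 100 cases, the real data included. There was 1 call in the real data and at most 37 in a permuted draw. That share was under 0.05, but it does not exclude chance for the presence of a call. The permutation moved residuals over all 12 arrays, which takes the arrays as independent and equally variable. The permutation did not keep the replicate numbers, by which the Holstein-Friesian arrays correlated with no label that explains it. Whether these numbers pair the arrays is undecided. With the replicate block no probe set passed by limma, and PCOLCE had an adjusted p of 0.1. The interaction test also singled out 11 gene lists by camera, and none with an estimated correlation (adjusted p = 0.13 to adjusted p = 0.605 with an estimated correlation). With the index as a covariate 5 of the 11 kept their call and 6 lost it. The Brahman effect exceeded the Holstein-Friesian effect by a median of 0.52 for collagens and matrix, 0.57 for the cell cycle and 0.36 for growth genes that decline after birth. It was lower by -0.67 for inflammatory cytokines, -0.70 for macrophages, -0.62 for MHC class II, -0.47 for matrix proteases, -0.68 for skeletal muscle, -0.37 for melanocytes, -0.80 for immediate early and heat shock genes and -0.18 for oxidative phosphorylation. The muscle difference lay in the naive animals, where Brahman exceeded Holstein-Friesian by 0.67 through naive Brahman 2 and 3 (levels 0.79 and 1.29, against -0.74 in array 1), while the infested breeds differed by 0.07. With all arrays the cell cycle and macrophage differences also lay more in the naive animals: naive Brahman differed by -0.38 and 0.41 and passed, and infested Brahman by 0.19 and -0.19 without passing. Without the 2 arrays of lowest index the macrophage median between the infested breeds was -0.515 and passed (adjusted p = 0.0163 by camera). That setting dropped infested Brahman 1, the infested Brahman array with the highest macrophage level (1.173, against 0.445 and 0.527). It also left the index of infested Brahman animals 1.33 log2 below that of infested Holstein-Friesian animals. Without infested Holstein-Friesian 2 the difference in the effect was 0.06 for inflammatory cytokines, -0.46 for macrophages, -0.38 for MHC class II and -0.27 for matrix proteases, and none of these lists passed. The immediate early median was then -0.34 and passed (level 1.16 in that array, against -0.27 and -0.22 in arrays 1 and 3), and was -0.27 without passing with the index as a covariate. Melanocytes did not pass without the 2 arrays of lowest index (-0.21, adjusted p = 0.112), nor oxidative phosphorylation without infested Holstein-Friesian 3 (-0.15). The collagen median was 0.19 without infested Brahman 3, and the cell cycle median 0.36 without naive Brahman 3. With all arrays the collagen list differed by -0.232 between the naive breeds, of unequal age, and by 0.238 between the infested breeds. Permuted residuals gave at least 11 lists in 20 of 100 cases, with at most 17, so chance is not excluded for the number of lists. The signal of control probe sets, outside the comparisons, also stood apart: the 5' minus 3' index was -3.18 in infested Brahman animals, below every naive array.

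More probe sets passed for infestation in Brahman (4753) than in Holstein-Friesian animals (1206), a contrast of counts that is not itself a test of the breeds. Infested Brahman 1 alone is argued against as the source of the larger changes. Without it 2.21 times as many probe sets changed at least 2-fold, passing or not, in Brahman as in Holstein-Friesian animals. That count cannot settle the excess of passing probe sets, since all arrays share 1 estimate of the spread. Without infested Brahman 1, 2563 probe sets passed in Holstein-Friesian animals. Lower RNA integrity passed its test and may account for part of the excess. A set of 2532 Brahman calls moved by under 0.5 log2 in infested Holstein-Friesian 2 and 3. Of these, 80.5% deviated in infested Holstein-Friesian 1, which has low 5' signal, with the sign of the Brahman change. When array 2 or 3 took its place, the share was 39.5% of 1876 and 50.0% of 2086. Those 2 shares are no independent baseline, because their reference arrays include infested Holstein-Friesian 1. A stronger response of the Brahman breed stays open, as do age and 5' signal, which differ between the same groups.

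The inflammatory list was lower in infested Brahman than in infested Holstein-Friesian animals, by a median of -0.91, with no member called (adjusted p = 0.456 with an estimated correlation). Lower RNA integrity stays open. The median was -1.20 without the 2 arrays of lowest index, but the index of infested Brahman animals then still lay 1.33 log2 below that of infested Holstein-Friesian animals, against 1.61 with all arrays. With the index as a covariate the median was -0.278 and the list did not pass. The difference may also rest on 1 animal, because the median was 0.012 without infested Holstein-Friesian 2. A breed difference in inflammation stays open as a hypothesis that 3 animals per group do not settle.

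The collagen and matrix list was higher in infested animals of both breeds by camera (adjusted p = 0.0538 in Holstein-Friesian and adjusted p = 0.0286 in Brahman animals with an estimated correlation). RNA integrity as the whole cause is argued against in Holstein-Friesian animals, where the median was 0.57 without infested Holstein-Friesian 1. In Brahman animals the median was 1.18 with the index as a covariate, and the list passed. That cannot decide the question in Brahman animals, because every infested array lay below every naive array in the index. The covariate also leans on infested Brahman 1, with the lowest index and a list level of 0.588, against 0.947 and 1.07 in infested Brahman 2 and 3. Age cannot be told apart from infestation, since infested animals were the youngest; the list was lower by -0.232 in the older of the naive groups, naive Brahman, but the infested breeds, of the same age, differed by 0.238. Growth genes that decline after birth passed in Brahman animals, with 6 of 16 members higher and none lower (median 0.49, adjusted p = 0.00205 by camera, 3.39e-05 by fry; adjusted p = 0.0741 with an estimated correlation). In Holstein-Friesian animals 3 of 16 were higher and none lower, and the list passed by fry but not by camera (median 0.05, adjusted p = 0.0139 and 0.166; adjusted p = 0.351 with an estimated correlation). A younger dermis and a matrix response to ticks both remain as hypotheses.

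Splits of the 6 arrays of a comparison into other groups of 3 number 10 with the real one, too few for a share under 0.05. For infested against naive animals, 1 of 10 splits gave as many probe sets as the real one in Holstein-Friesian (1206, highest other 0) and 1 of 10 in Brahman animals (4753, highest other 1). Among naive breeds it was 1 of 10 (6, highest other 0). Among infested breeds 3 of 10 splits gave at least 40 probe sets, the highest with 660, where infested Holstein-Friesian 1 was grouped with infested Brahman 2 and 3, which points to a structure of the arrays other than breed. For gene lists, 2 of 10 splits gave at least the 16 of Holstein-Friesian animals (highest other 19) and 5 of 10 the 8 of Brahman animals (highest other 11). Among naive breeds 9 of 10 gave at least 6 (highest other 13), and among infested breeds 1 of 10 gave 10 (highest other 8).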

How the results depend on the processing

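The 2 settings that concern the 5' signal, namely leaving out infested Holstein-Friesian 1 and infested Brahman 1 or taking the index as a covariate, and the replicate block in 6 arrays were chosen after the results were seen. Counts of changed probe sets are given in the order infested against naive Holstein-Friesian, infested against naive Brahman, difference between breeds, naive breeds and infested breeds, where they moved by over 1.5 times from 1206, 4753, 1, 6 and 40. Array weights gave 4589, 7657, 648, 400 and 1082. Leaving out the 2 arrays of lowest index gave 4076 in the first and 1131, 66 and 2200 in the last 3. The index as a covariate gave 2022, 1808 and, for naive breeds, 17. Only the 6 arrays of a comparison, with fewer degrees of freedom, gave 3000 in Brahman animals, 64 for naive and 1 for infested breeds. The low-signal filter gave 25 for infested breeds, cyclic loess 2 for the difference, the trended and robust prior 13 for naive breeds, and the replicate block 0 for the difference. The block, tried because same-numbered Holstein-Friesian arrays correlated, gave 1047 in that breed with 12 arrays and 1397 with 6. Without 1 array, where a group of 2 is left, the Holstein-Friesian count ranged from 157 to 2563: it was 157, 321 and 576 without naive Holstein-Friesian 1, 2 and 3, 734 without naive Brahman 2, 510 and 275 without infested Holstein-Friesian 2 and 3, and 2563 without infested Brahman 1. The Brahman count ranged from 2216 to 5567, with 3154, 2702 and 2216 without naive Brahman 1, 2 and 3. The difference between breeds ranged from 0 to 390: 390 without infested Holstein-Friesian 1, 15 without naive Brahman 1, 13 and 2 without infested Brahman 1 and 3, 1 without infested Holstein-Friesian 2 and 0 without any other array. Naive breeds ranged from 5 to 37, with 37 and 10 without naive Brahman 1 and 2, 16 without infested Holstein-Friesian 1, and 22, 11 and 14 without infested Brahman 1, 2 and 3. Infested breeds ranged from 11 to 1235: 1235, 11 and 15 without infested Holstein-Friesian 1, 2 and 3, 156 without infested Brahman 1, 24 and 25 without naive Holstein-Friesian 1 and 3, and 26, 25 and 26 without naive Brahman 1, 2 and 3. The counts of lists, 16, 8, 11, 6 and 10, became 0, 1, 0, 0 and 0 with an estimated correlation. Fry gave 1, 1 and 2 in the last 3 comparisons, and the covariate 5 for the difference and 1 for infested breeds. Without 1 array they ranged from 12 to 18, 6 to 11, 7 to 15, 6 to 10 and 6 to 11, with 7 for the difference and 6 for infested breeds without infested Holstein-Friesian 2, and 10 for naive breeds without naive Holstein-Friesian 2. The inflammatory list changed sign without infested Holstein-Friesian 2, to 0.062 for the difference (range without 1 array -1.029 to 0.062) and 0.012 for infested breeds (-1.339 to 0.012). For infested breeds complement changed to 0.017 without infested Brahman 2 (-0.321 to 0.017), and epidermal differentiation to 0.015 with the covariate. Over the settings, calls of named genes were kept 1280 times and lost 342 times in Holstein-Friesian animals, and 1553 and 366 times in Brahman animals, and none reversed. The PCOLCE difference between breeds lay between 1.88 and 2.18 in all 20 settings, and its call was kept in 11 and lost in 9 (adjusted p from 0.00113 to 0.119). The cause was not tested.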

Other observations

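The lists and tests in this part were fixed beforehand, except the settings that concern the 5' signal, which were chosen after the results were seen. Interferon-stimulated genes had medians of 0.26 in Holstein-Friesian and 0.37 in Brahman animals and did not pass with all arrays (adjusted p = 0.0803 and 0.096 by camera). Without the 2 arrays of lowest index they passed in Holstein-Friesian animals (median 0.40, adjusted p = 0.0172, 3 members higher and 1 lower) but not in Brahman animals (0.24, adjusted p = 0.146). They also passed in Holstein-Friesian animals without naive Holstein-Friesian 2 or 3, infested Holstein-Friesian 1 or naive Brahman 3, and in Brahman animals without naive Brahman 3 (0.46), without infested Brahman 2 (0.40) or with the index as a covariate. The median was 0.14 in Holstein-Friesian animals without naive Holstein-Friesian 1, and 0.24 in Brahman animals without naive Brahman 1. Epidermal differentiation genes had medians of 0.01 and -0.18 and did not pass. Only 19 of the 40 genes of that list were matched to a probe set, and KRT1, FLG and IVL were not. Antimicrobial and acute phase genes had medians of -0.12 and 0.04 and did not pass, with members in both directions: CD14, a receptor for bacterial lipopolysaccharide, rose 4.67-fold and 2.81-fold, while PGLYRP1 fell in both breeds. The acute phase gene SAA3 fell 5.94-fold in Brahman animals, where the naive arrays spread with an SD of 1.63. That fall was 11.4-fold without naive Brahman 1 and 8.99-fold without infested Brahman 3, and SAA3 did not pass without naive Brahman 2 or 3, or infested Brahman 1 or 2.

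Glandular epithelium did not pass as a list in either breed (adjusted p = 0.0706 in Holstein-Friesian and 0.218 in Brahman animals, with medians of -0.18 and -0.07), but passed in Holstein-Friesian animals without naive Holstein-Friesian 2 or naive Brahman 2. Of its members, KRT19 fell 4.56-fold in Holstein-Friesian and 6.34-fold in Brahman animals, AZGP1 3.83-fold and 7.10-fold, and KRT18 3.00-fold and 5.07-fold, with 5 of 23 members lower and 1 higher in the first and 6 lower and 2 higher in the second. AQP5 went the other way in Brahman animals. The lipid genes THRSP and PPARG fell 5.21-fold and 2.84-fold in Holstein-Friesian and 6.88-fold and 4.003-fold in Brahman animals, while the lipase LPL rose 4.99-fold in Brahman animals. The T cell genes CD8A and LCK rose 2.12-fold and 1.73-fold in Brahman animals, though probe sets of LCK disagreed and the list did not pass (adjusted p = 0.096), but did without naive Brahman 3 or infested Brahman 3.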
